A study of Caenorhabditis elegans with 3 samples.

How the data were processed

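The data were ChIP-seq peak lists from whole L1 larvae of Caenorhabditis elegans strain OP201, which carries the wgIs201 transgene with GFP-FLAG-tagged PQM-1. There were 3 biological replicates in 1 group, numbered as in the labels. Chromatin was fragmented by sonication, per the labels. No paired analysis was possible because there was only 1 group. A total of 1 control file used for peak calling, per the README deposited with each sample, was not analysed here.

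Peaks were called on each replicate and on the pooled alignments of all 3, on genome builds ce10 and ce11, per the README deposited with each sample. The relaxed lists, which include background peaks as input for IDR, held exactly 30000 peaks each. The IDR-thresholded lists were derived from the pooled and replicate lists, per the same source. The peak caller, the aligner and the IDR threshold are not given in the sources used here. Column 7 of the deposited lists holds the signal of each peak as the authors' caller gave it. Its scale differs between lists, so it was used only to rank peaks within a list. Column 9 of the deposited lists was treated as a score: it held small negative values in the pooled list and stood at its ceiling of 2.90 in 402 IDR peaks on each build, so it was not used to rank. Most peaks of a list had the same width, which was 290 bp in the pooled and IDR lists and 330, 310 and 240 bp in replicates 1, 2 and 3 on ce11.

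All positions are on ce11, 1-based, and coordinates were not converted between builds. Sequence was taken from the WBcel235 reference, the same assembly as ce11, and genes from Ensembl release 115. Every ce11 peak ended within the length of its reference chromosome. Of the genes in the lists, elt-5, hsp-16.11 and hsp-16.49 had no entry of that name in the annotation.

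The lists, the tests, the words, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. An IDR peak counted as found in a replicate when a peak among that replicate's 682 highest by signal, as many as there were IDR peaks, covered at least 50% of it. Chance was measured with 1000 random circular shifts within chromosomes. The promoter window reached from 1000 bp upstream to 200 bp downstream of any annotated 5' end of a protein-coding transcript. Location classes were assigned in the order promoter, 5' UTR, coding exon, 3' UTR, intron, non-coding gene and intergenic, and compared with random genome positions. Words were searched on both strands within 50 bp of the summit and of a point 500 bp away, on a side drawn at random, and tested with an exact McNemar test. Gene lists were tested with Fisher's exact test, two-sided, against the 19973 protein-coding genes on the nuclear chromosomes, and chromosomes with an exact binomial test against their length. Adjusted p-values are Benjamini-Hochberg values over 7 words, 30 lists or 6 chromosomes.

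The 30 lists covered markers of the intestine, body muscle, pharynx, neurons, hypodermis and germline, and gene families of secretion, defence, metabolism, stress, translation and chemoreception. The named genes were the 20 protein-coding genes with the highest-ranked IDR peak in the promoter window among peaks in the top lists of all 3 replicates, the 4 bound members with the highest-ranked peak of each list above expectation past an adjusted p of 0.05, and 12 genes named whatever their values, which were pqm-1, unc-119, daf-16, sod-3, mtl-1, hsp-16.2, vit-2, elt-2, hif-1, skn-1, clec-41 and asp-12.

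The alternatives were other numbers of top peaks, other overlap rules, other promoter widths, other word windows, the 341 highest-signal peaks, peaks in all 3 top lists, peaks in the top lists of each pair of replicates, the nearest gene alone, a background without tightly spaced genes, and expectation by gene number. Intervals and p-values treat peaks or genes as independent and cover counting of peaks only. They do not cover sequencing depth, which is unknown, or differences between larval cultures beyond the 3 replicates.

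The word, overlap and list functions were tested on simulated data. Of 600 simulated peaks, 39.5% were given TGATAAG and 39.8% were found with it, and of 59.7% given a matching replicate peak, 59.7% were found. The matching peaks kept their coordinates and the rest were moved away, so that recovery was fixed in advance. Of 30 simulated lists over 6000 genes, the 1 enriched list was called. The other lists held no bound gene by construction, so the simulation does not measure false calls. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.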

Results

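PQM-1, a zinc-finger transcription factor of the nematode Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole first-stage (L1) larvae of mixed sex. The strain carried a transgene for PQM-1 with a C-terminal GFP-FLAG tag, in a background mutant for unc-119. There was 1 group with 3 biological replicates, so the comparisons were between replicates, between peaks and the rest of the genome, and between gene groups. Each deposited replicate list held 30000 peaks ranked by a signal value. The authors also deposited a list of pooled peaks kept by the irreproducible discovery rate (IDR), a procedure based on how consistently peaks are ranked. The ce11 IDR list held 682 peaks, which were the 682 highest-signal peaks of the pooled list. Membership thus followed pooled rank and does not show that a peak was found in each replicate. The ce10 list held 652. Read counts and depths were not given in the files, so the depth of each replicate is unknown.

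Of the 20 highest-signal IDR peaks, 9 lay in no promoter window of a protein-coding gene, and the others lay near genes of varied kinds. The highest-ranked peak with a protein-coding promoter was 451 bp upstream of srz-62, a chemoreceptor-family gene (chromosome IV, 3899975 to 3900105), with a rank of 2.67 ± 1.53 (SD, n = 3) in the replicate lists. Peaks upstream of fbxc-29, an F-box gene (II, 915288 to 915577; mean rank 4.33 ± 2.08, SD, n = 3), and of lbp-3, a fatty acid-binding protein gene (X, 3256821 to 3257110; 9.0 ± 2.65, SD, n = 3), followed. The peak of clec-78, a C-type lectin gene, had a mean rank of 10.3 ± 0.577 (SD, n = 3), and that of prk-2, a Pim-family kinase gene, had a mean rank of 10 ± 7.94 (SD, n = 3). The prk-2 summit lay 4 bp downstream of an annotated 5' end (III, 3370060 to 3370349).

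Among the 20 genes with the highest-ranked promoter peaks found in the top lists of all 3 replicates, 18 had the summit upstream of the 5' end and 9 had TGATAAG within 50 bp of the summit. The others named by this rule were T24E12.13, frm-10, a FERM-domain gene, nspc-17, Y75B8A.28, F54E2.1, ZK185.3, madf-6, C29H12.2, B0507.3, T21D12.7, F27E5.9, ZK550.2, sem-5, an SH2/SH3 adaptor gene, tba-2, an alpha-tubulin gene, and cpr-4, a cathepsin B-like protease gene. Their signal values, as the authors' caller gave them, reached from 74.7 at cpr-4 to 181.6 at srz-62. The strongest peak of the list, with a signal of 225.1, lay in no promoter window. It was intergenic on chromosome IV (13919321 to 13919485), 6375 bp from the nearest protein-coding gene, Y37A1A.2, held TGATAAG, and ranked 2, 1 and 1 in replicates 1, 2 and 3. The peak ranked 17, on X (13937467 to 13937756), lay in an intron of elt-3, which encodes a GATA factor of the hypodermis. Both peaks were singled out after their values were seen.

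Of the genes fixed for reporting whatever their values, elt-2, which encodes the main GATA factor of the intestine, and clec-41, a C-type lectin gene, had an IDR peak in the promoter window. The elt-2 peak (X, 10480743 to 10481032, 352 bp upstream) ranked 365 in the IDR list and 557, 166 and 577 in replicates 1, 2 and 3. The clec-41 peak ranked 385, with replicate ranks of 5301, 337 and 72. At skn-1, an IDR peak ranked 610 lay in the gene body and outside the promoter window. No IDR peak lay within 1000 bp of daf-16, sod-3, mtl-1, hsp-16.2, vit-2, hif-1, asp-12 or unc-119. Each had a lower-ranked peak there in at least 1 relaxed list. The best ranks ran from 849 at hsp-16.2 to 22138 at sod-3, both in replicate 2. Absence from the IDR list thus does not show that these genes are unbound. The nearest gene of the IDR peak ranked 69 (V, 20778288 to 20778577) was hif-1, 1974 bp away. The pqm-1 locus itself (II, 11150391 to 11152595) had no peak in the IDR, pooled or any replicate list.

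The IDR peaks were found unequally in the replicates. A peak covering at least 50% of the IDR peak lay among the 682 highest-signal peaks of replicate 1 for 454 (66.6%, 95% exact binomial interval 62.9 to 70.1), of replicate 2 for 389 (57.0%, 53.2 to 60.8) and of replicate 3 for 215 (31.5%, 28.1 to 35.2). The mean was 51.7% ± 18.1 (SD, n = 3). Random circular shifts of the peaks gave means of 0.223%, 0.212% and 0.156%, and the permutation p for each replicate was 0.000999, the smallest that 1000 shifts can give. The pooled list holds the reads of each replicate, which the shifts ignore, so overlap above them was built in and is no independent evidence of replication. All 3 top lists held 100 of the peaks (14.7%), such as those at srz-62 and cpr-4, 227 were in the top lists of 2 replicates, 304 in that of 1 and 51 in none. Of the 171 highest-signal IDR peaks, 50.3% were found in all 3 top lists, against 7.06%, 1.18% and 0% in the next 3 bins of 170, 170 and 171 peaks. In the whole lists of 30000 peaks, 677, 661 and 537 IDR peaks were found in replicates 1, 2 and 3, and the pept-1, acs-2 and elo-9 peaks were among those absent from replicate 3.

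**Figure D1:**
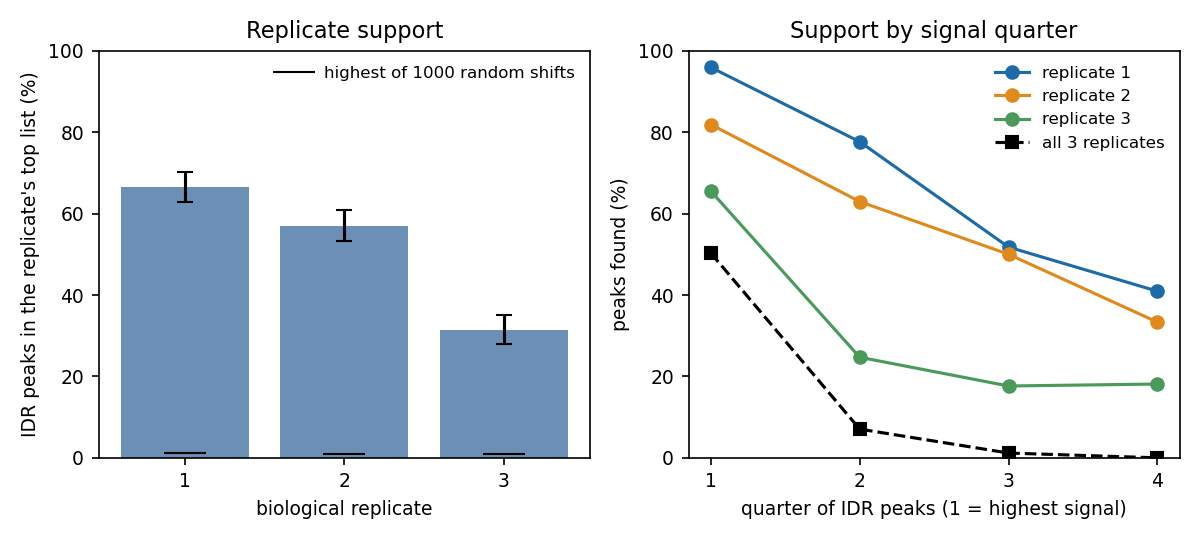
Left, percent of the 682 IDR peaks found among the 682 highest-signal peaks of each replicate, with exact binomial 95% intervals that cover peak counting only and a dash at the highest of 1000 random shifts. Right, the same percent in 4 bins of IDR peaks from highest to lowest signal, per replicate and for all 3 together, which runs from 50.3% to 0%.

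Ranks of the IDR peaks were compared between replicates. Spearman's rho across peaks was 0.140 for replicates 1 and 2, 0.172 for replicates 1 and 3 and 0.138 for replicates 2 and 3. The IDR peaks were the highest of the pooled signal, which narrows the range of ranks and lowers rho, so these values do not measure the relation over all peaks. Peaks are not independent replicates, and no p-value was taken from them. Of each replicate's own 682 highest-signal peaks, replicates 1 and 2 shared 264 (38.7%), replicates 1 and 3 shared 140 (20.5%) and replicates 2 and 3 shared 132 (19.4%). The act-5 peak shows the spread for a single gene, with ranks of 120, 8362 and 39.

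Promoters held more than their share of the peaks. The summit of 371 of the 682 peaks (54.4%, 95% exact binomial interval 50.6 to 58.2) lay between 1000 bp upstream and 200 bp downstream of the 5' end of a protein-coding transcript, against 26.2% ± 1.67 (SD over 1000 random shifts), and the two-sided permutation p was 0.002, the smallest the shifts can give. Coding exons outside these windows held 17 summits (2.49%) and introns 108 (15.8%), where random genome positions gave 18.8% and 27%. Intergenic sequence held 163 (23.9%, against 21.6%). The windows with a summit belonged to 435 of 19973 protein-coding genes, and the summit lay upstream in 402 of them. Over all 435 the median position was 221 bp upstream, with quartiles 461 and 110 bp upstream. At 70 peaks the summit lay in the windows of more than 1 gene, as at spp-2 and spp-6, so the gene bound there is not resolved.

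GATA words marked the summits. TGATAAG, known as the DAF-16-associated element, lay within 50 bp of 260 of 682 summits (38.1%, 95% exact binomial interval 34.5 to 41.9) and in 1.32% of windows 500 bp away from the same peaks (exact McNemar test, adjusted p = 1.25e-68 over 7 words). The shorter TGATAA was at 62.0% of summits and 9.97% of flanks (exact McNemar test, adjusted p = 8.43e-82), and WGATAR, the general GATA-factor word, at 71.3% and 21.6% (exact McNemar test, adjusted p = 3.25e-72). TGTTTAC, the DAF-16 binding element, was at 1.61% of summits and 1.61% of flanks (exact McNemar test, adjusted p = 1). The E-box CACGTG was at 4.11% and 1.91% (exact McNemar test, adjusted p = 0.0415), and this call ended in the 100 peaks found in all 3 top lists, at 2.00% and 1.00% (exact McNemar test, adjusted p = 1). The reversed control words GAATAGT and CATTTGT, at 1.03% and 2.79% of summits, did not pass (exact McNemar test, adjusted p = 1 for both).

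The peaks of lower signal held TGATAAG about as often as the strongest. It was at 40.9% of summits in the 171 highest-signal peaks (95% exact binomial interval 33.5 to 48.7) and at 38.2%, 34.1% and 39.2% in the next 3 bins, the last with an interval of 31.8 to 46.9. The named peaks of cpr-1, cpr-3, lys-2, spp-1, dhs-3 and elo-9 held it, and those of fat-4, lys-8, act-5 and pept-1 did not. Among the pooled peaks beyond the IDR list the share fell with rank, to 23.2% in the next 682 peaks.

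**Figure D2:**
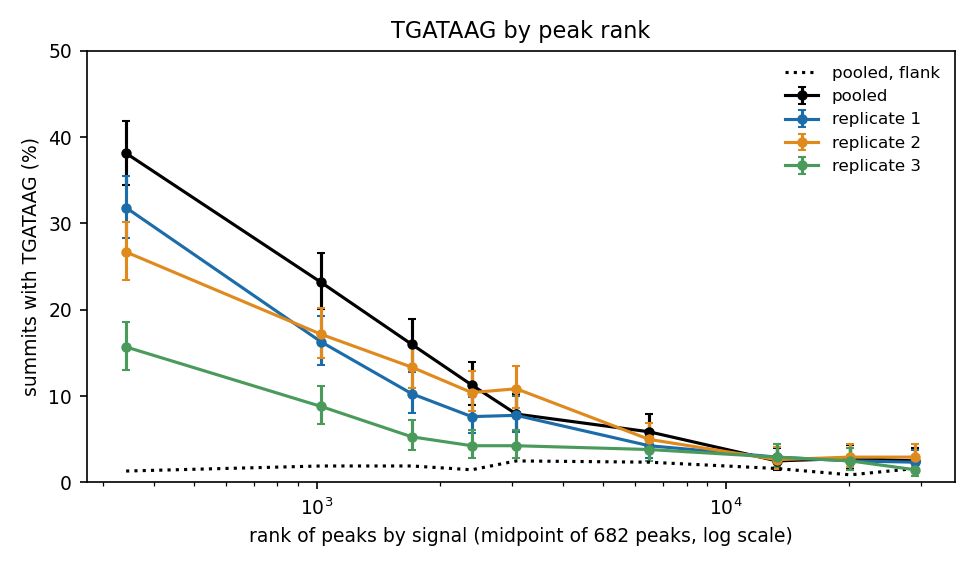
Percent of summits with TGATAAG in groups of 682 peaks by signal rank, on a log axis, in the pooled list and in each replicate, with exact binomial 95% intervals and a dotted line at the pooled flank share. In the pooled list it fell from 38.1% to 5.87% at ranks 6139 to 6820.

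**Figure D3:**
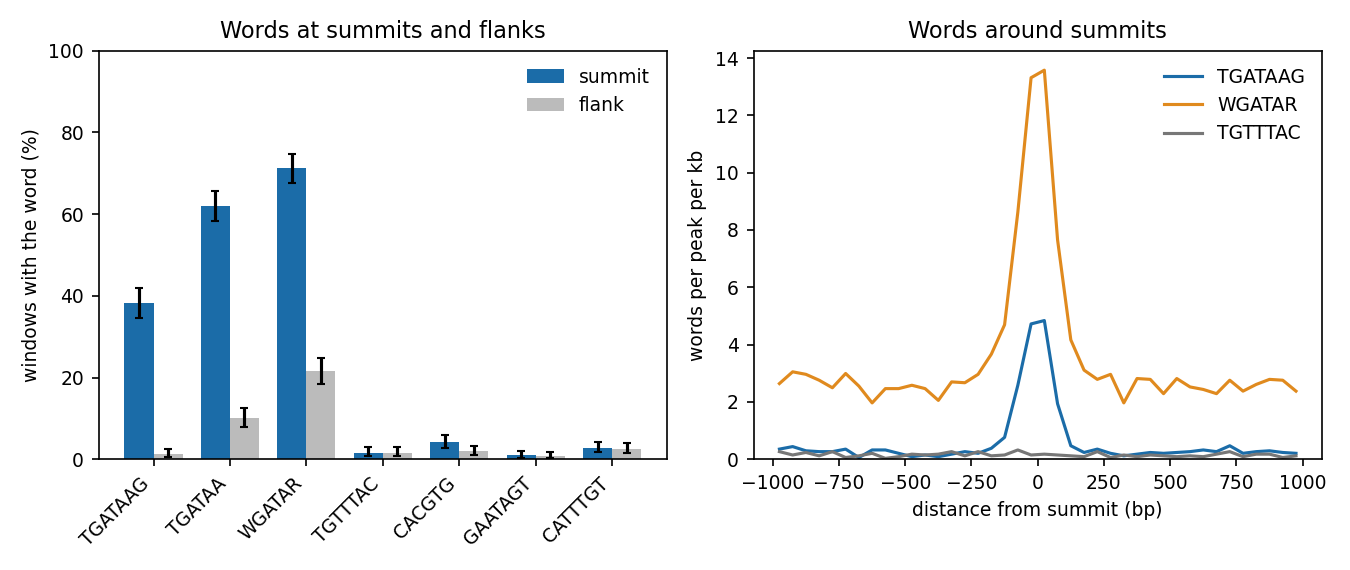
Left, percent of the 682 IDR peaks with each word within 50 bp of the summit and in windows 500 bp away, with exact binomial 95% intervals. Right, the number of words per peak and kb in 50 bp bins around the summit, which peaks at the summit for TGATAAG and WGATAR and not for TGTTTAC.

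Intestine markers and lysosomal proteases were bound more often than other genes. Of 18 intestine markers 6 had a promoter peak (33.3%, odds ratio 22.7, 95% interval 6.97 to 65.8; Fisher's exact test, adjusted p = 1.53e-05), where 2.18% of all protein-coding genes did. They were cpr-1, act-5, an intestinal actin gene, pept-1, a peptide transporter gene, asp-1, an aspartyl protease gene, elt-2 and eps-8. The eps-8 summit lay inside the gene, 125 bp downstream of a later annotated 5' end. The cpr-1 peak (V, 11975307 to 11975596) lay 99 bp upstream and ranked 66, 1823 and 397 in replicates 1, 2 and 3. Of 28 lysosomal proteases 5 were bound (17.9%, odds ratio 9.86; Fisher's exact test, adjusted p = 0.00187), namely cpr-4, cpr-3, cpr-1, cpr-9 and asp-1, of which cpr-1 and asp-1 are in both lists. The cpr-4, cpr-3 and cpr-9 peaks were in all 3 top lists, with mean ranks of 92.7 ± 93.8, 246.3 ± 215.1 and 299.3 ± 309.2 (SD, n = 3). The cpr-9 summit also lay in the window of gcy-33, so the gene bound there is not resolved.

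Lysozyme and antimicrobial genes and fatty acid metabolism genes were also bound above expectation. Of 77 lysozyme and antimicrobial genes 7 were bound (9.09%, odds ratio 4.55; Fisher's exact test, adjusted p = 0.00718), with lys-8 and lys-2, lysozyme genes, and spp-1 and spp-2, saposin-like genes, ranked highest. The lys-8 peak (II, 5585884 to 5586173) was in all 3 top lists, with a mean rank of 206.7 ± 247.2 (SD, n = 3). Of 31 fatty acid metabolism genes 4 were bound (12.9%, odds ratio 6.70; Fisher's exact test, adjusted p = 0.0188). They were fat-4, a fatty acid desaturase gene with a mean rank of 203.0 ± 194.8 (SD, n = 3), acs-2, an acyl-CoA synthetase gene, dhs-3, a lipid droplet dehydrogenase gene, and elo-9, a fatty acid elongase gene. The fat-4 summit lay inside the gene, 236 bp upstream of a later annotated 5' end.

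Ribosomal protein and chaperone genes formed another part of the bound set. Of 79 ribosomal protein genes 12 were bound (15.2%, odds ratio 8.24, 95% interval 4.03 to 15.5; Fisher's exact test, adjusted p = 4.02e-06), with rpl-3, rpl-15, rpl-20 and rps-20 ranked highest, at 55, 72, 80 and 167. The rpl-15 peak (IV, 654790 to 655079) was in all 3 top lists, at a mean rank of 206.3 ± 105.1 (SD, n = 3), while rpl-3 ranked 182, 63 and 18355. None of the 12 had TGATAAG within 50 bp of the summit, and at 9 of them the summit also lay in the window of another gene, so the gene bound there is not resolved. Of 24 heat shock and chaperone genes 5 were bound (20.8%, odds ratio 11.9; Fisher's exact test, adjusted p = 0.00108), with hsp-90, hsp-110, hsp-17 and hsp-1 ranked highest, and hsp-3 the last. At 2 of the 5, hsp-90 and hsp-110, the summit also lay in the window of another gene, C47E8.4 and rpn-3. The hsp-90 summit lay inside the gene, 417 bp upstream of a later annotated 5' end.

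Chemoreceptor genes were bound less often than other genes, at 6 of 1308 (0.459%, odds ratio 0.196, 95% interval 0.0714 to 0.431; Fisher's exact test, adjusted p = 5.42e-06), although srz-62 was among the strongest. No other list passed. The nearest were cuticle collagens, with 0 of 175 (Fisher's exact test, p = 0.0356, adjusted p = 0.133), C-type lectins, with 10 of 240 (p = 0.0430, adjusted p = 0.143 by Fisher's exact test) and UDP-glucuronosyltransferases, with 4 of 67 (Fisher's exact test, adjusted p = 0.175), namely ugt-62, ugt-64, ugt-20 and ugt-50.

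Markers of other tissues did not pass, with 1 of 15 pharynx markers (pha-4), 1 of 21 neuron markers (egl-21), 0 of 16 body muscle markers, 0 of 6 hypodermis regulators and 0 of 24 germline genes bound. Also without a pass were 10 of 322 F-box genes, 6 of 269 nuclear hormone receptor genes, 2 of 39 translation factor genes (eef-1A.2 and iff-2), 2 of 39 insulin-like peptide genes (ins-39 and ins-12), 2 of 44 glutathione S-transferase genes (gst-36 and gst-42), 1 of 63 ceh homeobox genes (ceh-37), 1 of 39 oxidative phosphorylation genes (cox-5A) and 1 of 10 dod genes (dod-21). No member was bound among 6 vitellogenin, 20 oxidative stress and metal, 20 insulin and FOXO pathway, 10 hypoxia, 74 cytochrome P450, 20 V-ATPase and 43 major sperm protein genes. For the small lists the intervals are wide, such as an odds ratio of up to 38.2 for the vitellogenins. Genes named here from lists that did not pass were chosen after their values were seen.

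With a window of 500 bp upstream the fatty acid share was 6.45% and the lysosomal protease share 10.7%, and neither passed (Fisher's exact test, adjusted p = 0.313 and 0.0553). With the nearest gene alone the ribosomal protein share was 7.59%, the chaperone share 12.5% and the chemoreceptor share 0.229%, all still past the threshold (Fisher's exact test, adjusted p = 0.0265, 0.0455 and 2.93e-07), and UDP-glucuronosyltransferases passed as well, at 7.46% (Fisher's exact test, adjusted p = 0.0455). In the 341 highest-signal peaks the chaperone share was 8.33%, the lysozyme and antimicrobial share 1.30% and the chemoreceptor share 0.382%, and none passed (Fisher's exact test, adjusted p = 0.129, 1 and 0.0641). These peaks bound 209 of 19973 genes, against 435 for all IDR peaks, so the share over all genes was lower too.

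Most list calls were lost in the smaller sets of peaks found in more than 1 replicate. Of 19973 genes, 63 were bound in the 100 peaks in all 3 top lists. In the peaks shared by 2 top lists, leaving out replicate 1, 2 or 3, 83, 87 and 162 were bound. Over all IDR peaks 435 were. The share over all genes thus fell too, and a lost call does not by itself show weaker enrichment. Among the 100 peaks in all 3 top lists, lysosomal proteases alone passed, and with peaks shared by the top lists of 2 replicates, 1, 2 and 3 lists passed above expectation without replicates 1, 2 and 3. The intestine share was 5.56%, 16.7% and 11% without replicates 1, 2 and 3 and passed without replicate 2 alone (Fisher's exact test, adjusted p = 0.433, 0.000932 and 0.0689). The fatty acid share was 6.45%, 3.23% and 9.68% and passed without replicate 3 alone (Fisher's exact test, adjusted p = 0.0734, 0.638 and 0.0199). Chaperones, at 0%, 0% and 8.33%, lysozymes and antimicrobials, at 3.90%, 2.60% and 2.60%, and chemoreceptors, at 0.153%, 0.153% and 0.459%, passed in none of the 3. Lysosomal proteases, at 10.7%, 14.3% and 10.7%, passed in each. The ribosomal protein share was 2.53%, 1.27% and 10.1% and passed without replicate 3 alone (Fisher's exact test, adjusted p = 0.321, 0.974 and 7.56e-06).

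**Figure D4:**
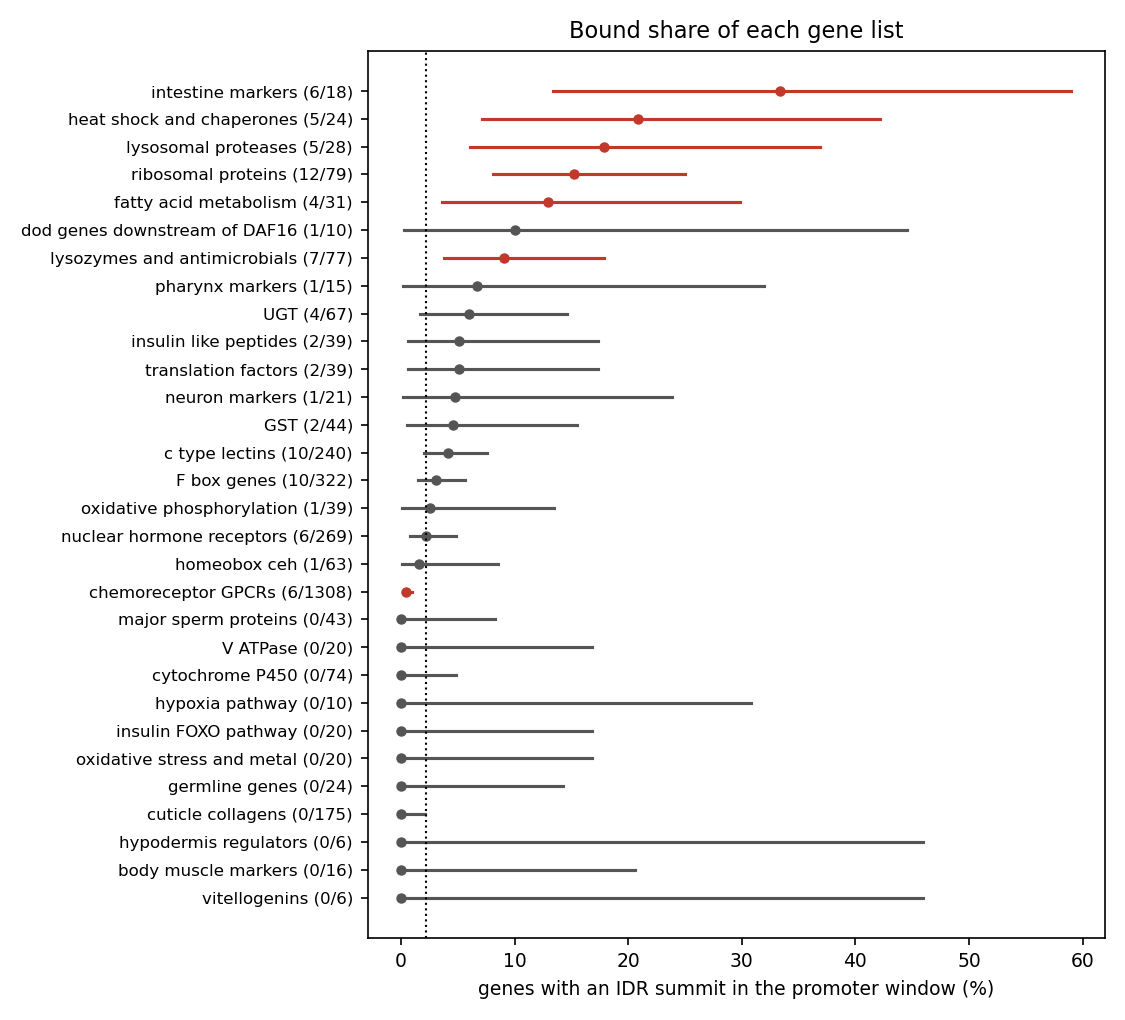
Percent of each of 30 gene lists with an IDR summit in the promoter window, with exact binomial 95% intervals and, in brackets, bound genes over members. Lists past an adjusted p of 0.05 by Fisher's exact test are in red, 6 above and 1 below the dotted line at 2.18%, the share over all protein-coding genes.

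The peaks were spread over the 6 nuclear chromosomes with no chromosome past the exact binomial test against chromosome length after Benjamini-Hochberg adjustment, and 1 at an unadjusted p under 0.05. That was chromosome I, with 83 peaks where 102.5 were expected (ratio 0.810; exact binomial test, p = 0.0366, adjusted p = 0.219). Chromosomes II, III, IV, V and X held 117, 105, 114, 134 and 129. Against the number of protein-coding genes 2 chromosomes passed, V with a ratio of 0.786 and X with 1.38 (exact binomial test, adjusted p = 0.00316 and 0.00086).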

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

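The shares below the authors' threshold were computed only after the IDR peaks had been examined. The pooled list reaches beyond the 682 IDR peaks, and TGATAAG at its summits stayed above the flank share there. It was at 23.2% of summits ranked 683 to 1364, against 1.91% of flanks, at 16% of those ranked 1365 to 2046, at 11.3% of those ranked 2047 to 2728, at 7.92% of those ranked 2729 to 3410 and at 5.87% of those ranked 6139 to 6820, against 2.35% of flanks in the last. At ranks 12959 to 13640 it was at 2.49% of summits and 1.61% of flanks (exact McNemar test, p = 0.345). At ranks 19779 to 20460 it was at 2.79% and 0.880% (exact McNemar test, p = 0.0146) and at ranks 28645 to 29326 at 2.49% and 1.61% (exact McNemar test, p = 0.345). No other groups of ranks were examined, and these p-values are not adjusted. The control word GAATAGT was at 0.733% of summits and 1.17% of flanks at ranks 683 to 1364, and at 2.64% and 1.32% at ranks 19779 to 20460 (exact McNemar test, p = 0.122).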

How the results depend on the processing

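The split of peaks by WGATAR and the ce10 count were chosen after seeing the data; the other alternatives were planned. TGATAAG, TGATAA and WGATAR stayed above the flanks and past the threshold under all 7 alternatives run for each, as did the promoter share, which ranged from 43.8% to 66.6% with the window. Mean replicate support was 78.1% with the top 5N peaks, and the peaks in all 3 top lists numbered 156 with 2N and 283 with 5N, since longer lists hold more peaks; over the sets that leave out a replicate the number ranged from 131 to 255, highest without replicate 3. The mean rank correlation ranged from 0.138 to 0.172 when a replicate was left out. CACGTG did not pass in the 100 peaks of all 3 top lists, at 2.00%, nor without replicate 1 or 2, with shares from 3.05% to 4.26% when a replicate was left out. The lists above expectation numbered 7 with the nearest gene alone, where UDP-glucuronosyltransferases newly passed, 5 among peaks with WGATAR, where C-type lectins newly passed and ribosomal proteins and chaperones no longer did, 4 with 500 bp upstream, where fatty acid metabolism and lysosomal proteases no longer passed, 4 in the 341 highest-signal peaks, where chaperones and lysozymes no longer passed, 1 in the 100 shared peaks, 1 to 3 when a replicate was left out and 2 among peaks without WGATAR, and the lists below numbered 0 in the 341 highest-signal peaks, in the 100 shared peaks and in each set that left out a replicate (0 to 0); the smaller sets and the narrower window bind fewer genes, and whether anything else ended the calls was not tested. The chaperone share turned to 0% in the 100 shared peaks and ranged from 0% to 8.33% when a replicate was left out. In these sets 63, 83, 87 and 162 genes were bound in all, against 435 over all IDR peaks. With so few bound genes, a share of 0% of 24 chaperones does not show a change of direction. The ribosomal protein share turned to 1.27%, against 1.39% of all genes, in peaks with WGATAR. Chromosomes past the threshold numbered 2 against gene number, and 0 to 1 when a replicate was left out; the cause was not tested. Other results for single lists, chromosomes and genes gave 373 values counted as kept, 28 that no longer passed and 6 that newly passed. For lists and chromosomes, kept meant the same direction and side of the threshold. For a gene it meant that leaving out a replicate moved the mean rank by less than its SD. With 3 replicates that always holds, so the gene values among the 373 do not show stability. A further 57 list shares, 6 chromosome ratios and 1 word share turned direction without passing in either setting. The list shares turned to 0% except nuclear hormone receptors at 1.12% (500 bp upstream), 2.23% (2000 bp), 2.02% (no tightly spaced gene), 0.372% (341 highest-signal peaks) and 0.743% (without WGATAR), and, at 2000 bp, hypodermis regulators at 16.7%, oxidative stress genes at 5.0%, hypoxia genes at 20% and homeobox genes at 3.17%, the last at 1.59% without WGATAR. With a replicate left out, the lists concerned ranged from 0% to 0.372% (nuclear hormone receptors), 6.67% (pharynx), 2.99% (UDP-glucuronosyltransferases), 2.27% (glutathione S-transferases) or, for the rest, stayed at 0%. GAATAGT turned to 2.35% with 100 bp windows, chromosomes II and IV to 0.993 and 1.02 against gene number, X to 0.996 in the 341 highest-signal peaks, and III and IV ranged from 0.889 to 1.14 and from 0.700 to 1.19 with a replicate left out. The unknown depth limits what an absent peak in a replicate shows.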

Other observations

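The tests by list of WGATAR, the bases beside TGATAA, the 6-base words, the share of the 502 unshared peaks of replicate 3 relative to shared peaks, the other gene families, CGATAA at ribosomal protein promoters and the 150 bp window were chosen only after the results above were seen. The bound promoters of the C-type lectin genes clec-78, clec-170, clec-265, clec-72, clec-41, clec-186, clec-62, clec-63, clec-67 and clec-43 all had WGATAR within 50 bp of the summit, which was not tested, and over all peaks the list did not pass. Among genes at peaks with WGATAR it passed (Fisher's exact test, adjusted p = 0.0204) with the same 10 genes, which follows from leaving out the other peaks and is no separate evidence. The genes clec-62 and clec-63 share 1 peak, and all 10 were chosen after their values were seen. At the summits TGATAA was followed by G in 48.5% of 652 sites, against 15.1% of 146 sites in the flanks (Fisher's exact test, adjusted p = 3.53e-13 over all bases and positions).

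Of the 682 peaks, 196 had no WGATAR within 50 bp of the summit, and 63.3% of these lay in a promoter window, against 50.8% of the 486 with it; the difference was not tested. In the 196, 57 of 2076 words of 6 bases were more frequent at the summit than in the flank and 29 less frequent after adjustment (exact McNemar test), with the words of the form WGATAR, absent by selection, left out. ACGCAG was at 15.8% of summits and 0.510% of flanks (exact McNemar test, adjusted p = 1.6e-05) and GAGAGA at 23% and 4.59% (exact McNemar test, adjusted p = 6.98e-05), and AAAATT was lower, at 17.3% and 42.9% (exact McNemar test, adjusted p = 0.000108). Many higher words were rich in G and C, such as CGCGCA, and many lower ones in A and T, such as TAAAAA. A difference in base composition between summit and flank was not separated from single words. Over all 682 peaks, which include the 196, ACGCAG and GAGAGA were also higher, at 7.62% and 15.5% of summits and 1.17% and 4.69% of flanks, and whether the peaks with and without WGATAR differed was not tested. In the 196, the GATA variant CGATAA was at 12% of summits and 2.04% of flanks (exact McNemar test, adjusted p = 0.00795). Over all 682 peaks it was at 13% and 2.64%. Among bound ribosomal protein genes 1 of 12, rps-15, had WGATAR at the summit, against 65.2% of the other bound genes (Fisher's exact test, adjusted p = 0.000567 over 6 lists). Chaperones, at 1 of 5, hsp-17, did not pass (Fisher's exact test, adjusted p = 0.182), nor did the intestine, protease, antimicrobial or fatty acid lists, at 83.3%, 60%, 71.4% and 75%.

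The peaks at ribosomal protein promoters, 9 of 12 of them also in the window of another gene, may owe their signal to something other than WGATAR. WGATAR was at 8.33% of their 12 summits (95% exact binomial interval 0.211 to 38.5), below the 68.5% at 356 other promoter peaks, the highest-ranked of each bound gene, and at 25% within 150 bp (5.49 to 57.2), against 85.7% at the others, which argues against WGATAR under or beside the summit at the rate of other promoters, and CGATAA was at 0 of the 12 (0 to 26.5). High expression with no site of the factor fits the low word share, whose interval includes the flank share of 21.6%. Strong transcription alone and other causes cannot be told apart by gene family, since 3.06% of 98 translation factor, oxidative phosphorylation and V-ATPase genes were bound (0.636 to 8.69), below 15.2%, while 20.8% of 24 chaperones were, and expression was not measured here. Open chromatin and binding through a partner stay open and were not tested, and no biological group in the design bears on them.

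The low share of IDR peaks found in replicate 3 was not a matter of peak width, since with summits within 100 bp it was 30.9%, against a mean of 60.2% in the others. A different set of GATA sites ranked highest is argued against by TGATAA at 30.4% of its own top summits (26.9 to 34), against 43.8% and 54.4% in replicates 2 and 1. The 502 top peaks of replicate 3 absent from the other top lists had TGATAA at 15.7% (12.7 to 19.2), above their flank share of 8.37%, which met the bound set beforehand against these peaks being mostly background. That bound can exclude only peaks with no sites at all: the excess was 12.1% (7.03 to 17.8) of the excess in the 180 shared peaks, where TGATAA was at 71.1%, so a candidate explanation is that some are bound sites and most are background, if unshared sites hold the word as often as shared ones, and if the flank and shared shares, held fixed in the interval, are exact. Unshared and shared top peaks had TGATAA at 48% and 62.2% in replicate 1 and at 32.5% and 58.3% in replicate 2, which does not separate background from sites with fewer words, and depth and immunoprecipitation efficiency stay open, with no biological explanation tested.

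No list held a peak at pqm-1, the gene carried by the transgene, in a peak-free stretch of 54.1 kb in the pooled list (II, 11118936 to 11172999) with 12 genes inside it. Chance is argued against, as 0.481% of protein-coding genes lie in a stretch as long, and 6 of 29994 gaps between pooled peaks were. A candidate explanation is extra copies of the locus in the control used for peak calling, which would need a stretch of at least 20 kb in every list, and the shortest, in replicate 2, was 43.3 kb. The lists rest on 1 control file, and the pooled list holds the reads of each replicate, so they are not separate support for it. Repeats cannot be told apart from extra copies, as 35.7% of the stretch is masked in the reference, between the genome's median of 32.3% and 95th percentile of 57.1% for stretches of that length. Removal of the region by the authors stays open too, and the control was not analysed here.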
